A study of Mus musculus with 2 samples.

How the data were processed

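The assay was chromatin immunoprecipitation followed by sequencing (ChIP-seq) with an antibody against histone H3 trimethylated at lysine 4 (H3K4me3), a mark found at the promoters of active and poised genes. The tissue was liver from B6NCrl mouse embryos of mixed sex at embryonic day 15.5. The labels gave 1 group with 2 biological replicates, a pool of 78 embryos for replicate 1 and a pool of 62 embryos for replicate 2. Replicate 1 had 1 technical replicate and replicate 2 had 2, and no second condition, stage or tissue was analysed here.

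The authors deposited 4 peak lists in narrowPeak form on mouse genome build mm10. Per the notes deposited with the samples, peaks were called on each replicate alone and on the pooled reads of both, and a replicated list was derived from these 3 lists. Every entry of the replicated list was an entry of the pooled list. Each peak carried a fold enrichment over control as a linear ratio, set by the authors' caller, and a −log10 q, also as deposited by the authors. It also carried a summit offset in bp from the peak's start, which the authors deposited as another field and which was used only when collapsing entries. These are the authors' own values per peak and served here only to describe, rank or filter peaks within a list. The aligner, the peak caller, its threshold and the rule for the replicated list are not given in the sources used here. The lists held peaks with a −log10 q under 2, so a lenient threshold had been used, and an alternative with a stricter one was run for most results. The number of reads behind each list is unknown, so a missing peak could not be told from a peak below the detection limit, and no interval based on reads was possible.

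Entries with identical coordinates were collapsed to 1 peak with the highest value. Coordinates were compared with the GRCm38 reference (mm10), whose names and lengths held every peak on the 21 chromosomes, and peaks on other contigs were set aside for the results on genes and on the TSS-proximal share. They stayed in the overlap of the replicates and in the count of kept pooled peaks, as distal peaks. Genes and transcription start sites (TSSs) came from GENCODE release M21, with 141730 transcripts, 132629 distinct TSSs and 21938 protein-coding genes on these chromosomes. RefSeq transcript starts for GRCm38 were used in an added alternative.

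A peak was called TSS-proximal when it lay within 1 kb of any annotated TSS and distal otherwise. A protein-coding gene was called marked when a replicated peak lay within 1 kb of the TSS of any of its transcripts. Replicated peaks at most 1 kb apart were joined into domains, a gene was given its widest domain within 1 kb of a TSS, and broad genes were the widest 5% of marked genes. A gene sharing a domain with a neighbour therefore got the neighbour's width too. Domain fold is the highest fold among the joined peaks. Widths measured in each replicate used that replicate's own list, and their mean and standard deviation (SD, n = 2) are the error given beside a domain width. Overlap of the replicates counted a peak as shared when at least 50% of its length was covered by peaks of the other replicate. Chance overlap came from 100 circular shifts of a list along each chromosome, with seed 1.

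The design compares no conditions, so no differential test was run. Each of 26 gene lists was compared with all other protein-coding genes by a two-sided Fisher's exact test, once for the marked share and once for the broad share among marked genes, with Benjamini-Hochberg adjustment over the 26 lists. These p-values are over genes of 1 tissue, which are not independent replicates of the tissue, and adjacent genes can share a peak. Fisher p-values under 1e-300 were set to 1e-300. Blood-lineage lists and hepatocyte lists were compared with each other by the same test. Shares carry Wilson 95% intervals, which cover the counting of peaks only. Promoter CpG content was the observed over expected CpG ratio within 500 bp on either side of the outermost 5′ end of a gene, compared between marked and unmarked genes by a two-sided permutation test with 100000 draws. A matched comparison set each list beside genes of the same CpG quintile with an exact test that summed hypergeometric distributions over the 5 quintiles. Near-identical copies of a TSS region were sought with minimap2, requiring at least 98% identity over at least 90% of the region within 500 bp of the outermost 5′ end.

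The gene lists, tests, thresholds, main definitions and 27 alternatives were fixed before the data were examined. The lists were written from textbook markers of the cell types a fetal liver can hold, of other tissues as contrasts, and of gene families, not from these samples. Of the members, 1 (Ahsp) had no identifier in the annotation used and 2 (H19 and Meg3) were not protein-coding and stayed out of the tests. There were 9 genes in 2 lists each. The rule for named genes was also fixed then. It took 9 anchor genes (Alb, Afp, Hnf4a, Gata1, Klf1, Tal1, Cyp7a1, Hbb-y and Snap25). From 8 lists (hepatocyte identity, mature hepatocyte metabolism, erythroid, globins, haematopoietic stem and progenitor, macrophage, endothelial and neuronal) it took the 3 members with the widest domains and the alphabetically first 3 unmarked members. From every other list it took the widest and the alphabetically first unmarked member. It also took the 10 widest domains with 1 gene per domain, the 5 distal peaks of highest fold, and the alphabetically first 5 list members marked in exactly 1 replicate. Some list members were left out for length, genes sharing a domain with a named gene are given with it, widest means widest in the replicated list, and other genes named outside the rule are said to have been chosen after their values were seen.

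Alternatives changed the overlap that counts as shared, the −log10 q minimum (2 or 5), the TSS window, the TSS set, the joining distance, the broad percentage, the CpG flank, and the list used (pooled, or the list of a single replicate, which leaves out the other). Alternatives with RefSeq starts, single-gene domains, the blood comparison without the erythroid list, and backgrounds matched on the highest CpG among a gene's TSSs or, for the broad share, on fold or CpG quintile were added after seeing the data. No paired fit was needed because there was 1 group.

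The code was tested on simulated data. Covered lengths equalled those from bedtools 2.31.1 for the 32814 peaks of replicate 1. In a simulated second list sharing 79.6% of them, a share of 79.6% was recovered. For the marked-share test over 21938 genes, 4% of 200 simulated lists of 25 genes drawn at random were called at an unadjusted 0.05 level, against 98% of lists with a true share of 95% and 93.5% of lists with a true share of 30%. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with minimap2 2.31 and samtools 1.23.1.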

Results

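H3K4me3 ChIP-seq was performed on mouse liver at embryonic day 15.5, a stage at which the organ holds both blood-forming cells and immature hepatocytes. The 2 biological replicates were pools of 78 and 62 embryos. Replicate 1 gave 32814 peaks covering 39.2 Mb and replicate 2 gave 32300 peaks covering 38.6 Mb. The pooled reads gave 32871 peaks (42.1 Mb), of which the authors kept 25809 (40.3 Mb) in the replicated list that the results below use. The fold enrichment of a peak is the authors' value, with a median of 10.2 in the replicated list. Read depth is unknown for every list, so an unmarked gene is one with no peak at an unknown depth.

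The first question was which genes of the cell types in fetal liver carried the mark at their promoters. Of 28 hepatocyte identity genes, which encode fetal and adult plasma proteins and the liver transcription factors, 27 were marked. Albumin (Alb, ENSMUSG00000029368.10) had a domain of 1.59 kb at chromosome 5, 90461524 to 90463110 (replicates 1.36 kb ± 0.165, SD, n = 2) with a fold of 3.51. Alpha-fetoprotein (Afp, ENSMUSG00000054932.6), the main fetal plasma protein, had 1.48 kb at chromosome 5, 90491359 to 90492836 (1.61 kb ± 0.421, SD, n = 2) with a fold of 5.06. Both domains began inside the gene and did not cover its outermost 5′ end, at 90460897 for Alb and 90490737 for Afp. Hnf4a (ENSMUSG00000017950.16), a nuclear receptor of the hepatocyte program, had 3.31 kb at chromosome 2, 163547164 to 163550473 (3.27 kb ± 0.0898, SD, n = 2) with a fold of 12.9. The widest domains of the list lay at Prox1 (7.96 kb), Foxa3 (5.79 kb, shared with Sympk) and Cebpa (5.49 kb), all transcription factors of liver development. Apoc3, an apolipoprotein, was the unmarked member. The marked share was above that of other protein-coding genes (Fisher's exact test, odds ratio 14.0, adjusted p = 7.08e-04), with 27 of 28 in each replicate. When a peak had to overlap the TSS itself, the share was 75% and the call was lost (adjusted exact p = 0.330).

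Most genes of mature hepatocyte metabolism had no peak. Only 9 of 32 were marked (28.1%, odds ratio 0.202, adjusted exact p = 1.05e-04), with 10 in replicate 1 and 9 in replicate 2. Cyp7a1 (ENSMUSG00000028240.2), the rate-limiting enzyme of bile acid synthesis, was unmarked in both replicates, as were Cps1 of the urea cycle and the drug-metabolising enzymes Cyp1a2 and Cyp2b10. The marked members included Pah (phenylalanine hydroxylase, 2.64 kb, fold 5.99), Arg1 (arginase of the urea cycle, 2.26 kb, fold 6.44) and Car3 (2.07 kb, fold 8.62). Against genes of the same promoter CpG quintile, which gave 8.76 marked genes by chance, the list did not stand apart (exact test, adjusted p = 1). Complement and coagulation genes had 21 of 25 marked (odds ratio 2.72, adjusted exact p = 0.102), among them antithrombin (Serpinc1, 3.64 kb), while C4bp was unmarked. Matched on CpG, 6.64 would have been marked by chance, and this list's excess then passed the test (adjusted exact p = 3.19e-09).

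The genes of red cell formation were nearly all marked. Of 27 erythroid genes 26 carried a peak (odds ratio 13.5, adjusted exact p = 9.26e-04), with 26 in each replicate. Gata1 (ENSMUSG00000031162.14), the master transcription factor of the lineage, had a domain of 8.91 kb at chromosome X, 7962922 to 7971826 (9.36 kb ± 0.607, SD, n = 2). Tal1 (ENSMUSG00000028717.12) had 10.3 kb at chromosome 4, 115055695 to 115066034 (11.0 kb ± 0.0255, SD, n = 2), and Klf1 (ENSMUSG00000054191.8), which activates the adult beta-globin gene, had 5.19 kb at chromosome 8, 84900586 to 84905773 (5.18 kb ± 0.252, SD, n = 2). Slc25a37, the mitochondrial iron importer of erythroblasts, was the unmarked member, and its TSS region has a copy of 100% identity on the same chromosome. In the heme and iron list 17 of 19 were marked (adjusted exact p = 0.0547), which passed for overlap with the TSS itself (adjusted exact p = 0.0309), at the outermost 5′ end (adjusted exact p = 0.0315) and at a −log10 q of at least 5 (adjusted exact p = 0.0493). Hamp, which encodes hepcidin, was unmarked there, and 4 of the 19 genes also stood in the erythroid list.

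Adult globin genes were marked and embryonic ones were not. The adult alpha genes Hba-a1 and Hba-a2 and the adult beta genes Hbb-bs and Hbb-bt were marked, 4 of 8 globins in all (Hbb-bs named after its values were seen, adjusted exact p = 0.517). The embryonic genes Hbb-y (ENSMUSG00000052187.4), Hbb-bh1 and Hba-x had no peak in either replicate, and neither did Hbb-bh2. Hba-a1 and Hba-a2 lay in 1 domain of 21.1 kb at chromosome 11, 32280810 to 32301912 (21.5 kb ± 0.939, SD, n = 2), which also held Hbq1a and Hbq1b. The TSS region of Hba-a2 has a near-identical copy, so the split of signal between the alpha genes is uncertain. Hbb-bt had 6.82 kb at chromosome 7, 103809242 to 103816059 (6.79 kb ± 0.0707, SD, n = 2).

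**Figure D1:**
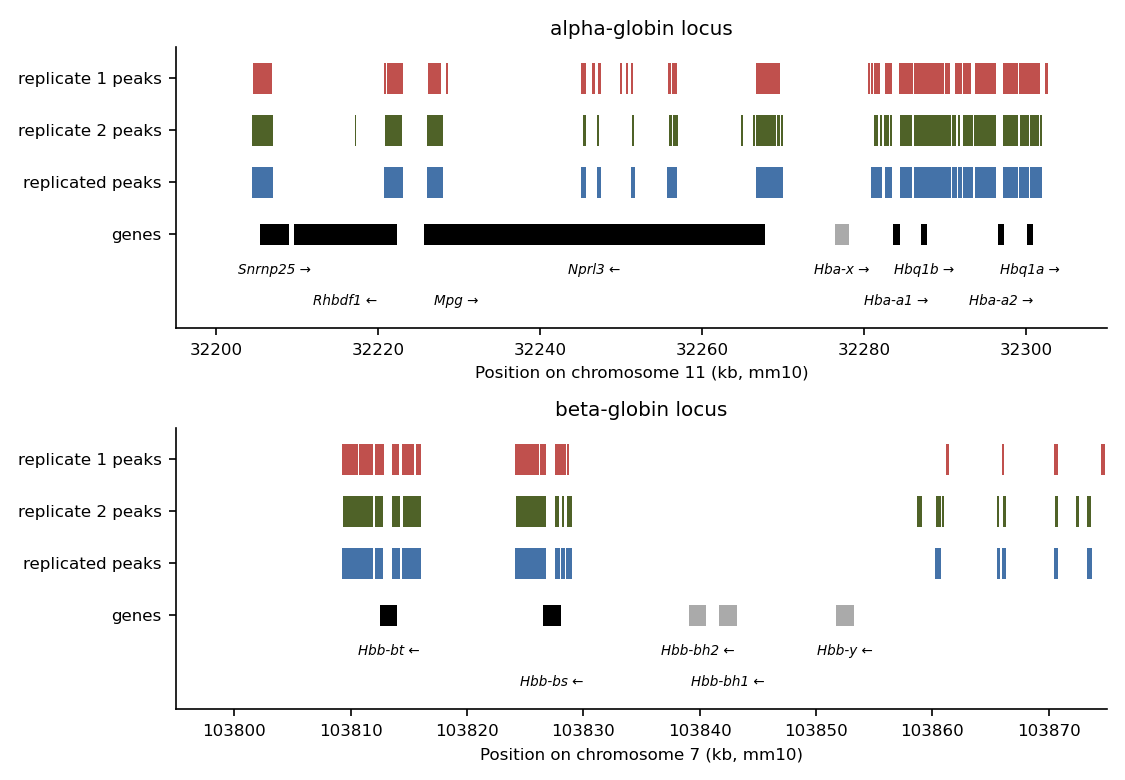
Map of peaks at the alpha-globin locus (chromosome 11) and the beta-globin locus (chromosome 7), with position in kb on the x axis and rows for the peaks of replicate 1, of replicate 2, of the replicated list, and for protein-coding genes. Marked genes are black and unmarked genes grey, with arrows for their strand. Among the globin genes, the peaks lie around the adult genes with gaps in the gene bodies. They flank the 5′ ends of Hba-a1 and Hba-a2 without covering them, and leave Hba-x, Hbb-bh1, Hbb-bh2 and Hbb-y bare. The TSS region of Hba-a2 has a near-identical copy, so reads there may not have been placed. The cause of the gaps was not tested, and a gap does not show that the mark is absent. Other peaks lie at Snrnp25, Rhbdf1, Mpg and Nprl3 and upstream of Hbb-y.

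Genes of blood stem and progenitor cells were also mostly marked, 23 of 25 (odds ratio 5.97, adjusted exact p = 0.0117), with 23 in each replicate. Lyl1 (9.33 kb, shared with Nfix and Trmt1), Lmo2 (8.26 kb) and Runx1 (7.67 kb), transcription regulators of blood stem cells, had the widest domains, and the thrombopoietin receptor Mpl and Slamf1 were unmarked. Megakaryocyte genes had 9 of 17 marked (adjusted exact p = 0.400), with Nbeal2 the widest at 6.61 kb (replicates 4.798 kb ± 2.76, SD, n = 2, and below Itga2b, named after its values were seen, in replicate 2) in a domain shared with Ccdc12 and Clec1b unmarked in the replicated list. That list passed as lower for overlap with the TSS itself (35.3%, adjusted exact p = 0.0385) and at the outermost 5′ end (29.4%, adjusted exact p = 0.0213). Macrophage and Kupffer cell genes had 11 of 21 (adjusted exact p = 0.340), and passed as lower for overlap with the TSS itself (28.6%, adjusted exact p = 0.00566) and at a −log10 q of at least 5 (38.1%, adjusted exact p = 0.0385). The iron exporter Slc40a1 (4.63 kb) and the transcription factors Maf (4.28 kb) and Mafb (3.82 kb) led that list, while C1qa, Cd163 and Cd5l were unmarked. Granulocyte and mast cell genes had 9 of 16 (adjusted exact p = 0.517), with Cebpe at 3.43 kb and Cpa3 unmarked. Lymphoid genes were marked less often than other genes, 4 of 14 for B cells (odds ratio 0.207, adjusted exact p = 0.0169) and 4 of 15 for T and NK cells (odds ratio 0.188, adjusted exact p = 0.00584). Ebf1, a regulator of early B cells, was marked over 3.83 kb and the T cell kinase Lck over 2.65 kb, and Blnk and Cd2 were unmarked. Against genes of the same CpG quintile neither lymphoid call held (exact test, adjusted p = 0.368 and 0.387).

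Of the other liver cell types, endothelial genes had 17 of 20 marked (adjusted exact p = 0.157), stellate and mesenchymal genes 14 of 20 (adjusted exact p = 0.816) and cholangiocyte genes 10 of 12 (adjusted exact p = 0.340). Esam (4.48 kb), the receptor Kdr (2.50 kb, replicates 2.64 kb ± 1.45, SD, n = 2) and Eng (2.06 kb) led the endothelial list, and Emcn, Lyve1 and Oit3 were unmarked. Hand2 (5.68 kb, replicates 5.23 kb ± 2.00, SD, n = 2, and below Pdgfra, named after its values were seen, in replicate 1) and Sox4 (4.98 kb) led the other pair, with Acta2 and Krt7 unmarked. All 22 cell cycle genes (adjusted exact p = 6.30e-04) and all 23 housekeeping genes (adjusted exact p = 4.46e-04) were marked. Against the same CpG quintile the housekeeping call held (20.3 of 23 by chance, adjusted exact p = 0.0444). Other CpG matches could not test these calls. The same CpG quintile gave 21.002 of the 22 cell cycle genes by chance, and genes matched on the highest CpG among their TSSs gave 21.9 of the 23 housekeeping genes, so that a fully marked list does not pass (adjusted exact p = 0.629 and 0.699). Imprinted genes had 14 of 15 marked (adjusted exact p = 0.0538), with Gnas the widest at 8.27 kb and Ndn unmarked, and passed at 2 kb (adjusted exact p = 0.00965), with RefSeq starts (adjusted exact p = 0.00966), for overlap with the TSS itself (adjusted exact p = 0.0290) and at a −log10 q of at least 5 (adjusted exact p = 0.0493).

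Genes of muscle, germline, epidermis and olfaction were marked less often than other genes. Muscle genes had 2 of 18 marked (odds ratio 0.0647, adjusted exact p = 2.06e-05), germline and testis genes 2 of 19 (odds ratio 0.0609, adjusted exact p = 1.18e-05) and epidermal genes 2 of 13 (odds ratio 0.0941, adjusted exact p = 8.77e-04). The marked Ckm of muscle shared its domain with Klc3, and the marked Gdf9 of oocytes shared its domain with Uqcrq, a gene of the respiratory chain. Acta1, Acrv1 and Cdsn were unmarked, and Krt10 was marked over 1.62 kb. That domain (chromosome 11, 99385357 to 99386981) lay over 1 kb from the outermost 5′ end of Krt10 at 99389364, so only another annotated TSS made it count. The epidermal call did not hold against genes of the same CpG quintile (exact test, adjusted p = 0.368). Only 3 of 1092 olfactory receptor genes were marked (odds ratio 0.00122, adjusted exact p at most 2.6e-299, set by the floor on p). The widest of them, Olfr56, shared its domain with Ifi47 and has a near-identical copy of its TSS region, and Olfr1 was unmarked. Neuronal genes had 10 of 21 marked (adjusted exact p = 0.160). Snap25 (ENSMUSG00000027273.13) of the synapse was unmarked in both replicates, as were Camk2a, Dcx and Gad1, and Slc17a7 (2.46 kb, replicates 1.41 kb ± 1.33, SD, n = 2), Eomes (2.16 kb) and Nefm (1.65 kb) were the widest, with Slc17a7 below the other two in replicate 2 (475 bp). Developmental regulators of other lineages had 16 of 22 marked (adjusted exact p = 0.680) and Hox genes 28 of 39 (adjusted exact p = 0.543). Pax6 (4.39 kb) and Hoxb2 (2.78 kb) were the widest of these, and Lhx3 and Hoxa10 were unmarked. Of 8 Y-linked genes 4 were marked (adjusted exact p = 0.517), with Ddx3y over 1.96 kb and Sry unmarked, in tissue pooled from both sexes.

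**Figure D2:**
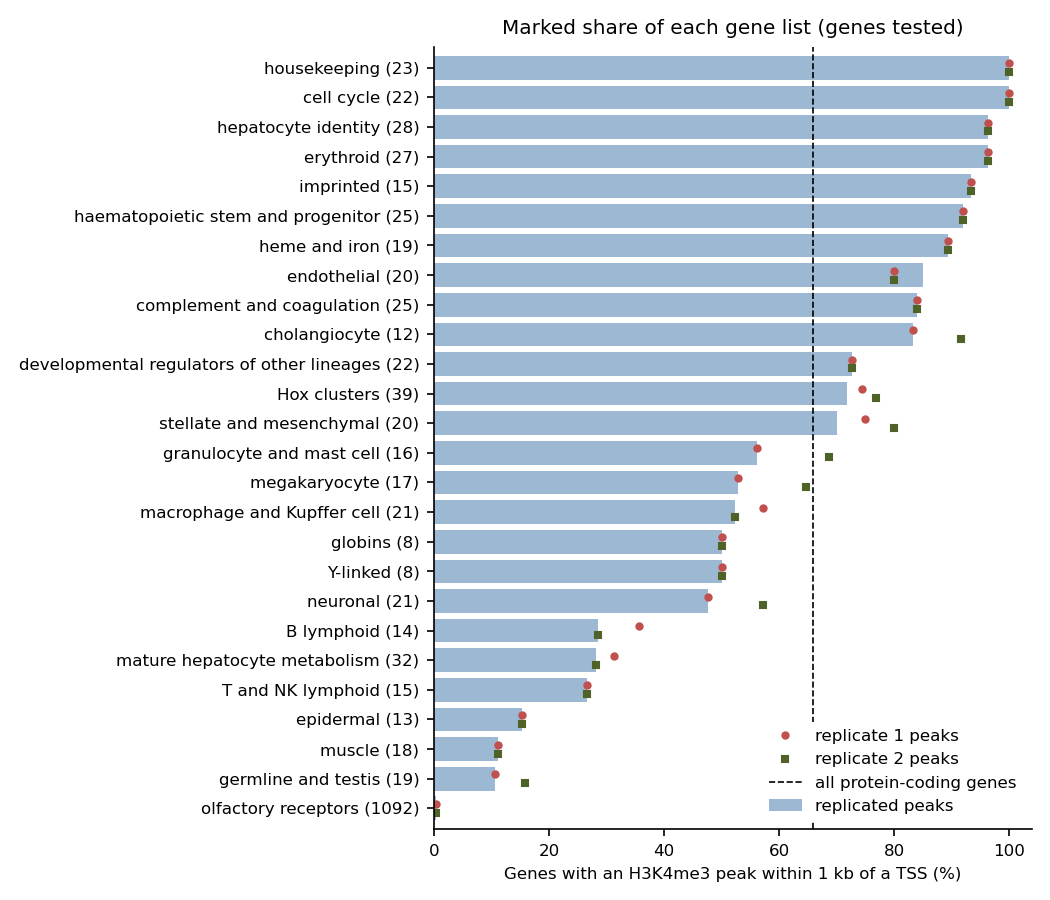
Share of each gene list with an H3K4me3 peak within 1 kb of a TSS (x axis, percent of the genes tested, whose number stands in brackets), for the replicated peaks (bars) and for the peaks of each replicate (points), with the share of all protein-coding genes as a dashed line at 65.9%. Erythroid and hepatocyte identity genes sit above 96% and mature hepatocyte genes at 28.1%.

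Across all 26 lists, 5 had a higher and 7 a lower marked share than other protein-coding genes, and 14 did not pass the test. In total 14448 of 21938 protein-coding genes (65.9%) were marked, with 14572 in replicate 1 and 14583 in replicate 2. Of the replicated peaks on chromosomes, 16966 of 25798 were TSS-proximal (65.8%, Wilson 95% interval 65.2% to 66.3%), against a mean of 10.2% when the peaks were shifted along the chromosomes. TSS-proximal peaks had a median width of 1812 bp and a median fold of 28.4, and distal peaks had 563 bp and 4.08. The share was lower in the replicates' own lists, 58.5% ± 0.332 (SD, n = 2).

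The second question was which genes carried the broadest domains. Erythroid genes stood out, with 20 of the 26 marked members among the widest 5% (over 5.75 kb) and a median width of 7.83 kb against 2.33 kb for all marked genes. Ank1, which encodes the ankyrin of the red cell membrane, had the widest domain of any coding gene at 27.7 kb, on chromosome 8 from 23033027 to 23060699 (27.9 kb ± 0.767, SD, n = 2). That rank depended on joining, since with touching peaks only Ank1 had 7.77 kb, 86 coding genes had more and Rbm38 had the most (15.6 kb). The Gata1 cofactor Zfpm1 had 16.6 kb, but 9.98 kb ± 2.27 (SD, n = 2) in the replicates' own lists, and Fech, the last enzyme of heme synthesis, had 13.1 kb (13.5 kb ± 0.474, SD, n = 2). Globins had 3 of 4 marked genes among the broad (median 14.0 kb), but Hba-a1 and Hba-a2 share 1 domain of 21.1 kb, which counts for both. Hbb-bt had 6.82 kb and Hbb-bs 4.91 kb, so no globin domain had a width near that median. Heme and iron genes had 9 of 17 broad (median 6.08 kb), stem and progenitor genes 7 of 23 (median 4.13 kb) and housekeeping genes 6 of 23 (median 3.65 kb). Hepatocyte identity genes had 2 of 27, Prox1 and Foxa3 (median 3.31 kb), and 1 in each replicate, and mature hepatocyte genes 0 of 9 (median 1.23 kb).

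The broad share of the erythroid list was above that of other marked genes (Fisher's exact test, odds ratio 65.0, adjusted p = 3.39e-20), with 19 broad members in replicate 1 and 20 in replicate 2. The excess passed the test too for heme and iron (odds ratio 21.6, adjusted exact p = 4.12e-07), globins (odds ratio 57.2, adjusted exact p = 0.00312), stem and progenitor genes (odds ratio 8.38, adjusted exact p = 8.02e-04) and housekeeping genes (odds ratio 6.75, adjusted exact p = 0.00388). It did not pass for hepatocyte identity (odds ratio 1.52, adjusted exact p = 1) or the 20 remaining lists. Among the latter, imprinted genes had 3 of 14 (adjusted exact p = 0.130), cell cycle genes 2 of 22 with Rrm2 at 9.62 kb, and megakaryocyte genes 1 of 9. The cell cycle list passed with touching peaks only (31.8%, adjusted exact p = 5.83e-04) and with the widest 10% (45.5%, adjusted exact p = 1.74e-04), and the imprinted list against marked genes of the same fold quintile (adjusted exact p = 0.00743). The 17 lists other than these, hepatocyte identity and the 5 that passed had 0 broad members. Without the 4 members it shares with the erythroid list, heme and iron had 6 broad of 14 marked genes (unadjusted Fisher's exact p = 3.27e-05). When peaks up to 3 kb apart were joined the calls for globins (50% broad, adjusted exact p = 0.122), stem and progenitor (adjusted exact p = 0.547) and housekeeping genes (adjusted exact p = 1) were lost. The globin call also ended with touching peaks only, at 0 broad members, and in single-gene domains (50% broad, adjusted exact p = 0.363). The housekeeping call ended with touching peaks only (adjusted exact p = 0.134), with the widest 2% (adjusted exact p = 1) and in single-gene domains (adjusted exact p = 0.186), and the stem and progenitor call with the widest 2% (adjusted exact p = 0.0678).

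**Figure D3:**
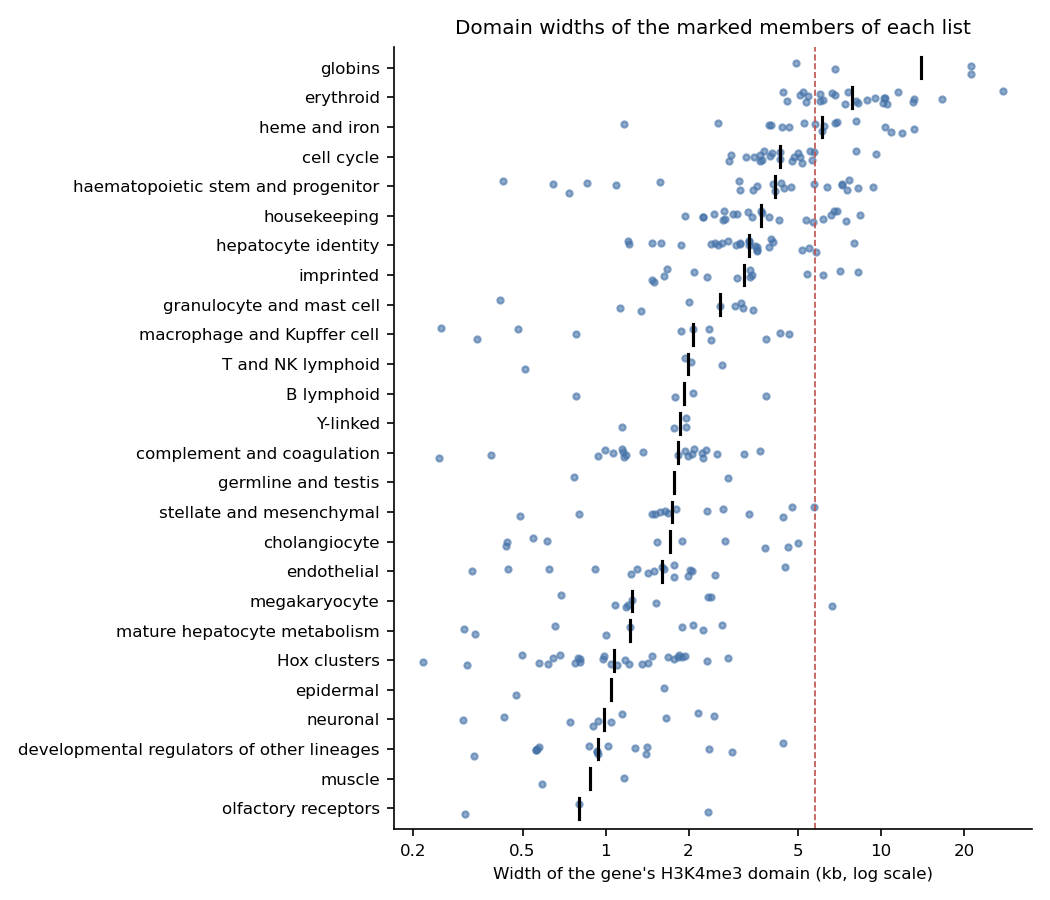
Width of the H3K4me3 domain of every marked member of each gene list (points, x axis in kb on a log scale, vertical jitter only for legibility), with the list's median as a black bar and the broad threshold of 5.75 kb as a dashed line. Erythroid genes (median 7.83 kb), heme and iron genes (6.08 kb) and globins (14.0 kb) have medians to the right of the threshold. The globin median counts the 21.1 kb domain shared by Hba-a1 and Hba-a2 for both genes and lies between it and Hbb-bt (6.82 kb).

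The 10 widest domains of coding genes included several outside the lists. After Ank1 and the alpha-globin domain came Rbm38 (20.7 kb, replicates 20.6 kb ± 0.163, SD, n = 2) and Ranbp10 (17.5 kb, 15.1 kb ± 3.25, shared with Tsnaxip1). A domain of 16.8 kb (16.6 kb ± 0.211, SD, n = 2) held the TSSs of Prdx2, a peroxidase abundant in red cells, of Junb, of Rnaseh2a and of Gm49661. Zfpm1 followed, then Epb41 (16.1 kb, 18.0 kb ± 1.70, shared with Gm10300), which encodes protein 4.1 of the red cell skeleton, Eral1 (15.7 kb, 15.7 kb ± 0.0382), Bmp2k (14.5 kb, 14.4 kb ± 0.0636) and Rhof (14.4 kb, 8.07 kb ± 8.85, shared with Setd1b). The errors are SDs with n = 2, and those of Rhof, Ranbp10 and Zfpm1 were the largest. In total 723 genes in 541 domains were broad, and 595 genes were broad in both replicates, of 728 in replicate 1 and 730 in replicate 2.

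Blood and hepatocyte lists were then compared directly. Among genes of the 5 blood lists (erythroid, stem and progenitor, megakaryocyte, macrophage, granulocyte), 78 of 105 were marked (74.3%), against 36 of 60 hepatocyte genes (60.0%). Of the marked genes, 28 of 78 blood genes were broad (35.9%) and 2 of 36 hepatocyte genes (5.56%). The difference in the broad share passed the test (Fisher's exact test, odds ratio 9.52, p = 4.56e-04) and did so in replicate 1 (odds ratio 18.7, p = 1.15e-04) and replicate 2 (odds ratio 17.2, p = 2.64e-04). The erythroid list carried it, with 20 of the 28 broad blood genes, and macrophage and granulocyte genes had 0. Without the erythroid list, a comparison added after seeing the data, 8 of 52 blood genes were broad (15.4%) and the difference did not pass (odds ratio 3.09, Fisher's exact p = 0.189), nor did it in replicate 1 (Fisher's exact p = 0.0759) or replicate 2 (Fisher's exact p = 0.143). The difference in the marked share did not pass in the replicated list (odds ratio 1.93, Fisher's exact p = 0.0793) or in replicate 1 (Fisher's exact p = 0.0778), and passed in replicate 2 (Fisher's exact p = 0.0193). The lists also differed in median domain fold, with 46.7 for erythroid, 10.1 for hepatocyte identity and 5.70 for mature hepatocyte genes. The broad-share comparison was not matched on fold, and the share of each cell type in the tissue is unknown here. A difference between lineages therefore cannot be told from a difference in cell share.

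Promoters of marked genes were richer in CpG. The observed over expected CpG ratio averaged 0.663 ± 0.228 (SD over 14448 marked genes) against 0.217 ± 0.156 (SD over 7490 unmarked genes), a difference of 0.445 (permutation test, p = 1e-05, the smallest that 100000 draws can give). From the lowest to the highest CpG quintile, 13.3%, 37.0%, 82.6%, 97.2% and 99.2% of genes were marked. Klf1 (ratio 0.0783) was marked with a ratio below the mean of marked genes, and Snap25 (0.549) was unmarked with a ratio above the mean of unmarked genes. Against genes of their own CpG quintile, erythroid genes had 26 marked against 14.2 by chance (exact test, adjusted p = 7.83e-09) and hepatocyte identity genes 27 against 12.4 (adjusted p = 1.33e-10). In the same comparison neuronal genes fell short, 10 against 15.6 (adjusted exact p = 0.00299), as did germline genes, 2 against 11.9 (adjusted exact p = 1.35e-09). Of the lists that had not passed, this matching brought past the threshold endothelial genes (17 against 11.7, adjusted exact p = 0.0101), heme and iron genes (17 against 10.6, adjusted exact p = 9.12e-04) and imprinted genes (14 against 10.5, adjusted exact p = 0.0154) above chance and Y-linked genes (4 against 6.08, adjusted exact p = 0.0447) below it. Matched on the highest CpG among their TSSs, heme and iron (adjusted exact p = 0.214) and imprinted genes (13.6 of 15 by chance, adjusted exact p = 1) did not pass. Matching turned the direction for 4 lists that then passed the test. Globins (3.08 times the chance number, adjusted exact p = 0.0429) and granulocyte genes (1.95 times, adjusted exact p = 0.0225) lay above chance, and developmental regulators (0.819 times, adjusted exact p = 0.0327) and Hox genes (0.837 times, adjusted exact p = 0.0154) below it.

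Distal peaks made up 8832 of the replicated peaks on chromosomes (34.2%). The 5 of highest fold lay nearest to the coding genes Sf3b5, Zfp292, Chd7, Chd2 and Ptma. The peak at Sf3b5, a splicing factor gene, covered chromosome 10 from 13007473 to 13010374 with a fold of 68.5, overlapped an exon, and lay 2130 bp from the nearest GENCODE TSS but over a RefSeq transcript start. The peak near Zfp292 (chromosome 4, 34885907 to 34887975, fold 63.1) lay 2947 bp from its TSS. That near Chd7 (chromosome 4, 8646676 to 8649012, fold 62.9) was 41394 bp from the Chd7 TSS and over the RefSeq start of Gm8273. Those near Chd2 (chromosome 7, 73616883 to 73619771, fold 61.9) and Ptma (chromosome 1, 86486648 to 86489225, fold 61.1) were intergenic, 75053 bp and 37501 bp away. Of all distal peaks 56.9% lay in the body of a coding gene, 34.1% lay over 10 kb from any TSS, and 10.8% lay within 1 kb of a RefSeq transcript start. Among the tenth with the highest fold (at least 12.4) that last share was 20.4%.

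The replicates were compared as the only sample comparison the design allows. Of 14776 genes marked in at least 1 replicate, 14379 were marked in both and 397 in 1, with 193 in replicate 1 and 204 in replicate 2. The genes marked in 1 replicate had a median width of 272 bp and a median fold of 2.97. Among the lists, 25 genes were of this kind, the alphabetically first being Acta2 (276 bp, fold 2.69), Barhl1 (567 bp, fold 4.36) and C1qa (180 bp, fold 2.77) in replicate 2 and Blnk (660 bp, fold 3.16) and C1qb (222 bp, fold 3.09) in replicate 1. Domain widths ranked alike across genes marked in both (Spearman's rho 0.944 across genes, which are not independent replicates), and 93.3% of these genes had widths within 1.5-fold of each other.

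**Figure D4:**
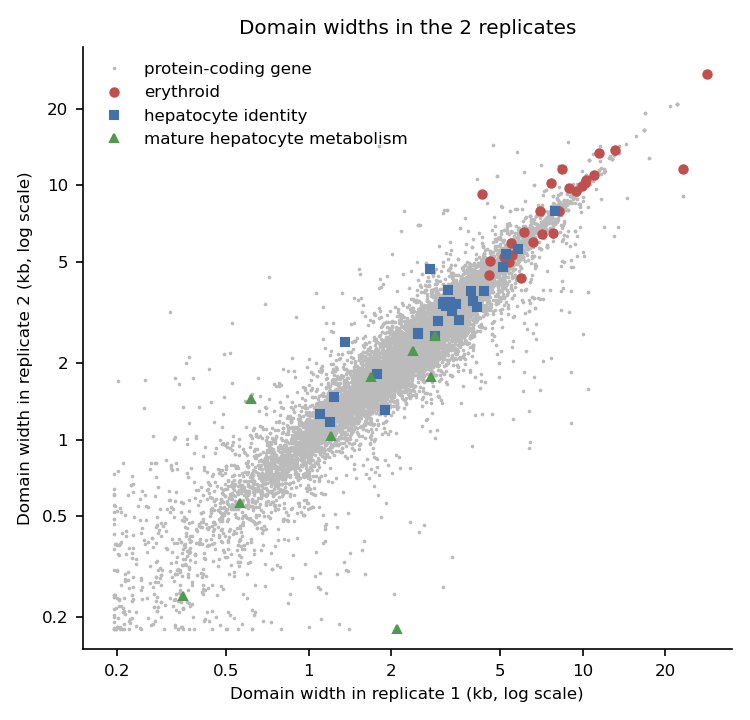
Domain width in replicate 1 (x axis) against replicate 2 (y axis), both in kb on log scales, for protein-coding genes marked in both replicates (grey) and for members of 3 lists (coloured). Ank1 lies at the top right, and the median difference between replicates is 1.09-fold.

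Of the TSS-proximal peaks, 88.0% in replicate 1 and 90.1% in replicate 2 were shared with the other replicate, against 61.9% and 63.5% of the distal peaks. Over all peaks 78.1% ± 1.40 (SD, n = 2) were shared, against 1.49% and 1.52% after shifting. Unshared peaks were narrow and weak, with median widths of 245 and 241 bp and median folds of 3.00 and 2.79, against 1117 and 1100 bp and 10.5 and 9.91 for shared peaks. Of the pooled peaks the authors kept 90.1% of the TSS-proximal and 63.0% of the distal ones in the replicated list (Fisher's exact test, odds ratio 5.36, p at most 1e-300), and the odds ratio was 3.02 when TSS-proximal meant within 2 kb. Kept peaks were wider and stronger than dropped ones (median 1192 against 227.5 bp, fold 10.2 against 2.49). Pooled TSS-proximal peaks were likewise wider and stronger than distal ones (1639 against 377 bp, 21.3 against 3.17). The odds ratio was not matched on width or fold, so place and peak strength cannot be told apart here. Nearly all pooled peaks covered over at least 50% of their length in both replicates were kept (23310 of 23312), and 2499 further peaks were kept by a criterion not given in the sources used here.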

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

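The results on genes and on the TSS-proximal share used peaks on the assembled chromosomes only. Outside them, 11 replicated peaks lay on 5 unplaced or unlocalized contigs, with a median width of 622 bp and folds from 1.73 to 46.7. The replicates' own lists held 13 and 12 such peaks. No gene of the annotation used was assigned to them, and no explanation was tested. They entered the replicate overlap and the count of kept pooled peaks, where they counted as distal. They are listed only because the results on genes leave these contigs out, and the data hold no control count to set them against.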

How the results depend on the processing

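The broad-share backgrounds matched on fold or CpG, the marked-share background matched on the highest CpG of a gene, the RefSeq starts, the single-gene domains and the blood comparison without the erythroid list were added after seeing the data, and the cause of the changes below was not tested. The erythroid broad share ran from 50% (widest 2%) to 92.3% (widest 10%) and passed the test under every alternative run, with 20 broad genes against 1.27 by chance from marked genes of the same CpG quintile (adjusted exact p = 1.32e-20). The counts of marked genes and of lists with a lower marked share, the CpG difference and the genes marked in 1 replicate also stayed on the same side of their threshold or within 1.5 times. Against the same CpG quintile, however, partly different lists made up the count of lower lists. Mature hepatocyte, B lymphoid (adjusted exact p = 0.368), T and NK lymphoid (0.387) and epidermal genes (0.368) no longer passed. Neuronal (adjusted exact p = 0.00299), developmental (0.0327), Hox (0.0154) and Y-linked genes (0.0447) passed as lower instead. The odds ratio for kept pooled peaks passed the test throughout and ran from 3.02 (2 kb window) to 8.03 (500 bp). The share of overlapping peaks in replicates 1 and 2 was 82.3% and 83.9% at 1 bp, 68.1% and 69.2% at a reciprocal 50%, 82.6% and 82.2% at a −log10 q of at least 2, and 92.5% and 89.5% at a −log10 q of at least 5. The TSS-proximal share was 62.3% within 500 bp, 72.0% within 2 kb, 56.9% for overlap with the TSS itself, 69.0% at a −log10 q of at least 5, 60.8% for protein-coding TSSs, 57.3% in the pooled list, 69.5% with RefSeq starts added, and 58.2% to 58.7% in the lists that leave out a replicate. Distal peaks fell to 4746 with a 5 kb window. The odds ratio for blood against hepatocyte marking was 1.89 to 2.38 in the lists that leave out a replicate, and past the threshold without replicate 1 only (Fisher's exact p = 0.0193). The odds ratio for the blood against hepatocyte broad share kept its side of the threshold except without the erythroid list (3.09, Fisher's exact p = 0.189). The number of lists with a higher broad share was 2 with 3 kb joining, 3 with the widest 2% and 3 in single-gene domains. The number with a higher marked share was 10 against the same CpG quintile and 8 against the same quintile of the highest CpG.

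Most changes of direction concerned lists that passed no test on either side. The marked share lay on the other side of that of other genes for stellate genes (65% at 500 bp, 55% for overlap with the TSS itself), developmental regulators (63.6% at 500 bp, 50% for overlap with the TSS itself, 54.5% at a −log10 q of at least 5), endothelial (45%), cholangiocyte (58.3%) and Hox genes (56.4%) for overlap with the TSS itself, Hox genes at the outermost 5′ end (51.3%), and granulocyte genes (68.8% in the pooled list, and without replicate 1 only in the 56.2% to 68.8% of the lists that leave out a replicate). The broad share did so for hepatocyte identity (3.70% in the pooled list and without either replicate), stellate genes (6.25% in the pooled list and without replicate 1, 7.14% with 3 kb joining and in single-gene domains, 14.3% for the widest 10%), cholangiocyte genes (20% for the widest 10%), granulocyte genes (11.1% with 3 kb joining), megakaryocyte genes (0% without replicate 1, with touching peaks only, with 3 kb joining, for the widest 2% and in single-gene domains) and globins (0% with touching peaks only). Against the same CpG quintile, and then the same quintile of the highest CpG, the marked number over the chance number was 1.03 and 1.04 for mature hepatocyte genes, 3.08 and 3.62 for globins, 1.29 and 1.503 for megakaryocyte, 1.46 and 1.60 for macrophage and 1.95 and 2.07 for granulocyte genes, all above 1. It was 0.819 and 0.775 for developmental regulators and 0.837 and 0.808 for Hox genes. Of these, globins, granulocyte, developmental and Hox genes passed the test under both backgrounds, and macrophage genes under the second (adjusted exact p = 0.0174), although macrophage genes passed as lower for overlap with the TSS itself (28.6%) and at a −log10 q of at least 5 (38.1%). Among the domain widths of named genes, 197 values under an alternative lay within 1 SD of the replicates and 139 did not. Of the 139, 43 came with touching peaks only, 30 without replicate 1 and 31 without replicate 2. The lists that leave out a replicate hold the same values that set the SD (n = 2), so those counts say little. Unknown read depth limits every count of unmarked genes. No paired analysis was possible because the samples form 1 group.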

Other observations

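The tests on gene families, the comparison of erythroid with housekeeping genes, the background matched on fold for the broad share, the single-gene domains and the search for a copy of the Slc25a37 TSS were chosen after the results were seen. Gene families also showed differences (11 families picked by symbol, Fisher's exact tests with Benjamini-Hochberg adjustment over the 11). Some members, such as Krt10, Rpl13a and Cyp7a1, also stand in the fixed lists. Replication-dependent histone genes were marked in 61 of 67 cases, and 44 of the 61 were broad (odds ratio 52.3, adjusted exact p = 4.38e-43), with 44 in each replicate. Their clusters are dense, and the 44 genes lay in 15 domains. Ribosomal protein genes had 80 of 83 marked and 10 of 80 broad (adjusted exact p = 0.0353), and all 75 mitochondrial ribosomal protein genes were marked with 0 broad (adjusted exact p = 0.0916). Zinc finger genes named Zfp had 320 of 365 marked (adjusted exact p = 6.24e-21) over a median of 1.82 kb, and proteasome genes 38 of 39 (adjusted exact p = 4.30e-06). Cytochrome P450 genes had 29 of 94 marked (adjusted exact p = 1.39e-11), keratins 7 of 49 (adjusted exact p = 3.25e-13), interleukins 7 of 37 (adjusted exact p = 9.50e-09) and vomeronasal receptors 1 of 327 (adjusted exact p = 1.48e-151). Solute carriers had 264 of 361 marked (adjusted exact p = 0.00330), and homeobox genes of the Nkx, Lhx, Dlx and Pax families 26 of 37 (adjusted exact p = 0.729).

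Runx1, Hnf4a, Gata2, Gfi1b, Lmo2 and Tal1, chosen after their values were seen, each had more than 1 group of TSSs. Every group was marked in both replicates, but this does not show separate marking of each group. All groups of Tal1 had the same highest fold (52.7), as did those of Gfi1b (54.6) and some of Runx1, Hnf4a and Gata2. A single peak can thus count for several groups. Runx1 and Hnf4a are described here. Runx1 carried peaks at its distal TSS group on chromosome 16 at 92825778 to 92826149 (fold 45.5) and at its proximal TSSs at 92695495 to 92697328 (fold 43.9), in both replicates. Hnf4a carried peaks at the TSS at 163506808 on chromosome 2 (fold 11.9) and at the group from 163546817 to 163547188 (fold 12.9), in both replicates. At the globin loci, 2 distal replicated peaks lay inside Nprl3, whose introns are known to hold alpha-globin enhancers, with folds of 2.61 and 3.33. Replicated peaks there within 1 kb of an annotated TSS were not counted. Among them were peaks at 32251226 to 32251702 (fold 2.85) and 32255667 to 32256922 (fold 3.69). Upstream of Hbb-y, in the region of the beta-globin locus control region, 5 distal replicated peaks lay on chromosome 7 between 103860256 and 103873711. Their folds were 2.51 to 5.95, and 2 of the 5 overlapped a peak of replicate 1 and 5 of replicate 2. Of 5134 lincRNA genes over 5 kb from a coding TSS, 421 (8.20%) were marked.

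The broad domains of erythroid genes were set against 3 explanations. In domains that touch a single coding gene, 22 of 25 marked erythroid genes were among the widest 5% of such domains (Fisher's exact p = 3.33e-26 among 11424 genes), so joining of neighbours does not account for the pattern. Among marked genes of the same fold quintile 1.497 broad genes were expected and 20 seen (exact p = 1.03e-20), which argues against peak height as the whole cause. If width followed only the share of cells carrying the mark, housekeeping genes, used in every cell, would be at least as broad. The erythroid list had the larger broad share (odds ratio 9.44, Fisher's exact p = 5.46e-04), so across these 2 lists width did not follow cell share alone. Both shares were known when this comparison was chosen, so its outcome was fixed. The lists also differed in median CpG ratio (0.291 for erythroid, 0.757 for housekeeping) and in median fold (46.7 and 59.7). The comparison therefore cannot decide how far cell share accounts for the difference from other cell types. Housekeeping genes also had a broad excess over other marked genes (6 of 23, odds ratio 6.75). A biological origin is a hypothesis only, since the design holds no second tissue or stage and no expression values were analysed.

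For the unmarked mature hepatocyte genes, low promoter CpG was considered first. Genes of the same CpG quintile gave 8.76 marked members on average against 9 seen (exact p = 1), so the list did not stand apart from them. That match cannot show that CpG content is the cause. Complement and coagulation genes had a similar median CpG ratio (0.19974 against 0.19788 for mature hepatocyte genes). Yet 21 of 25 of them were marked, against 6.64 by chance in the same CpG quintile. These values argue against low CpG alone being enough to leave such genes unmarked. Reads shared between copies would need most unmarked members to have a near-identical copy, and 2 of 23 did. Whether these genes gain the mark later was not tested, since the design has 1 stage. Stage therefore stays open.

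The unmarked Slc25a37 and Apoc3 differed. The TSS region of Slc25a37 has 1 near-identical copy, of 100% identity at chromosome 14, 69502862 to 69503862, so its lack of a peak may come from reads that could not be placed. Over all genes, 3.98% of 1056 with a copy were marked against 69.0% of 20882 without, and in the highest CpG quintile 55.2% of 29 against 99.5% of 4359. For Apoc3, 0 copies were found, which argues against that explanation. Its low CpG ratio of 0.130 was not tested as a cause.

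A further hypothesis was that broad domains spread into the transcribed gene. Reach was measured from the gene's most upstream TSS in or within 1 kb of the domain. With several TSSs this choice lengthens the downstream side, so an even split is no neutral expectation for the binomial test. Broad single-gene domains reached a median of 5.56 kb downstream and 1.31 kb upstream of that TSS, other single-gene domains 1.465 kb and 0.551 kb. Of the 403 broad ones, 89.6% reached farther downstream (exact binomial p = 2.25e-64). However, 91.8% of the 11021 other single-gene domains did so too (odds ratio 0.771, Fisher's exact p = 0.118). The condition set beforehand for rejecting the hypothesis, a share not larger than in other domains, was therefore met. That condition was wrong, as seen only with the result, since the measure was near its ceiling in both sets and ignores how far a domain reaches. Spread into the gene and the general position of the mark cannot be told apart here.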
